A study of Mus musculus with 16 samples.

How the data were processed

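RNA sequencing of mouse spermatozoa was analysed from 16 libraries, 8 from males on a high-fat diet (HFD) and 8 from males on a control diet (CD). Per the labels' protocols, males started the diet at 3 weeks of age and stayed on it for 9 weeks. Motile sperm were then isolated, lysed with sonication and extracted with a column kit, and 2 ng of RNA was treated with DNase and turned into double-stranded cDNA with a whole-transcriptome amplification kit. Libraries were built from 250 ng of cDNA. The series describes each diet as 8 mice, so libraries were treated as separate animals. Amplification from so little RNA makes copies, and no molecular identifier is named in the labels, so copies cannot be told from separate molecules in the counts.

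The deposited table holds raw read counts per gene symbol, not normalised, with 1 column per library. The submitters' processing notes name STAR, HTSeq 1.0.0, DESeq2 1.0.19 and the mm10 genome build, with no role or order. The gene annotation and the strand setting of the counting are not given in the sources used here, so reads of a gene and of a gene overlapping it on the other strand cannot be told apart. The table has 24062 gene rows and 5 summary rows of the counting program. Of the gene symbols, 22977 matched GENCODE M21 or RefSeq for GRCm38, the assembly that mm10 denotes. It has 0 mitochondrially encoded genes, so that class was not analysed here. A gene was given a position only where its symbol matched 1 GENCODE gene, which held for 103 of the 105 named genes, and 51 of these overlap another annotated gene.

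The summary rows were kept out of library sizes and tests. Between 8.02% and 20.1% of the reads in a library's column were assigned to genes, 58.0% to 76.1% to no annotated feature, and 15.8% to 30.7% were not uniquely aligned. Reads ambiguous between features made up 0.0474% to 0.0907%. Gene counts ranged from 1882555 in HFD 4 to 7783981 in CD 2. Pairs of libraries of one diet were compared by chi-square over genes, and the 56 pairs gave values of 13.6 to 187 per degree of freedom, so no library was a second copy of another of its diet. Pairs across diets were not compared in this way.

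Diets were compared with edgeR 4.0.16 in R 4.3.3, using its quasi-likelihood F-test with robust estimation, trimmed mean of M-values (TMM) factors and its default expression filter by diet. Diet was the sole term of the model, tests were two-sided, and Benjamini-Hochberg adjustment ran over the 13149 genes that passed the filter, with a threshold of 0.05. CPM were computed from the deposited counts on 2 scales. For single genes they are edgeR's, over the genes that passed the filter and with library sizes multiplied by the TMM factors. For summed lists, and for Gpx5 and the genes listed beside it, they are counts scaled to each library's gene total, so a gene's CPM is not a part of its list's sum. Rn45s is given as a share of gene counts. The step was tested on simulated data made from these libraries' means, dispersions and sizes, with 200 of 13149 genes changed. It recovered 3 of 50 genes changed 2-fold, 34 of 50 changed 4-fold, 39 of 50 changed 8-fold and 42 of 50 changed 16-fold, with 8 false calls. With no gene changed it made 0 calls. Simulated genes were drawn independently of each other, so correlated genes and libraries that stand apart in many genes at once were not covered.

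Gene lists were fixed before the data were examined: 28 lists of germ cell stages, other cell types that a sperm preparation could hold, and cell processes. Lists with at least 5 tested genes were compared with camera (limma 3.58.1), with the correlation between genes estimated per list. Library composition was compared for 31 measures with exact permutation tests over the 12870 assignments of libraries to diets, on summed CPM as log2(CPM + 1) for lists. The overall profile was compared by a permutation test of the pseudo-F on Euclidean distances of log2 CPM with a prior count of 2. The rule for named genes, also fixed beforehand, took genes past the threshold, the genes with the smallest unadjusted p up to 20 if fewer than 10 passed, the 15 most abundant genes, and up to 3 of the most abundant tested members of each list. It named 105 genes, some of which are not reported here. Prm1, Tnp1, Gpx5 and the initial segment and caput genes listed beside Gpx5 were added after their values were seen.

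Alternatives covered the test (DESeq2 1.42.0, limma-voom with quality weights, edgeR without robust estimation), scaling, low-count filters, ribosomal RNA left out, surrogate variables (sva 3.50.0), the log2 total as a covariate, title numbers as a block, another distance, the 500 most variable genes, rank statistics, a preset correlation of 0.01, the rotation test fry, and leaving out each library. Added after the data were seen were the comparison without HFD 4 and HFD 8, the ratio of sperm to epididymal transcripts as a covariate, edgeR's newer quasi-likelihood fit, and mean CPM of a diet without the library with its highest value. Library measures and figures used Python 3.11.15 with scipy 1.17.1.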

Results

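Sperm RNA of 16 male mice was sequenced, 8 after a high-fat diet (HFD) and 8 after a control diet (CD). The series asks how paternal obesity bears on the early embryo, and these libraries address which transcripts of sperm differ with the diet of the male. Gene counts per library ran from 1882555 in HFD 4 to 5153818 in HFD 2 among HFD libraries, and from 3172721 in CD 8 to 7783981 in CD 2 among CD libraries. Between 15004 genes in HFD 4 and 17796 in CD 2 had at least 1 count.

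Transcripts of the epididymal epithelium, the duct lining in which sperm mature, were among the most abundant in these preparations. Of the 15 genes with the highest mean CPM, Crisp1, Cuzd1, Adam7, Rnase9 and the lipocalin Lcn5 belong to the fixed epididymal list. The protease inhibitor Spink8 is also known from that tissue. Crisp1, a sperm-coating secretory protein, stood at 10566 CPM ± 5056 (SD, n = 8) in HFD and 10414 ± 4103 (SD, n = 8) in CD. Spink8 had 10348 CPM ± 5303 in HFD and 12133 ± 3891 in CD, Adam7 5455 ± 3058 and 6016 ± 3376, Rnase9 3465 ± 2148 and 3955 ± 2598, and Cuzd1 6859 ± 3271 and 7620 ± 1571. The precursor of ribosomal RNA, Rn45s, took 2.31% of gene counts in CD 2 and 24.1% in CD 8. Wfdc13, Malat1, Gpx3, Eef1a1, Itm2b, AY761185, Clu and B2m made up the rest of the 15, and edgeR's quasi-likelihood test gave these genes adjusted p from 0.676 for Eef1a1 to 0.988 for Crisp1.

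Sperm transcripts varied widely between libraries of one diet. The 40 genes of the late spermatid list, which encode protamines, flagellar and acrosomal proteins, summed to 34901 CPM in HFD 4 and 69302 CPM in HFD 8, while the other 14 libraries held 3258 to 17375 CPM. In the same 2 libraries the epididymal list summed to 12621 and 10780 CPM, against 30677 to 80393 in the other 14. Meiotic genes, such as those of the synaptonemal complex, summed to 4716 and 3855 CPM in HFD 4 and HFD 8 and to at most 1458 CPM elsewhere. Prm1, the protamine that packs sperm DNA, and Tnp1, a transition protein that precedes it, averaged 1731 CPM ± 3322 and 1122 ± 2215 in HFD (SD, n = 8) and 541 ± 462 and 261 ± 202 in CD. HFD 8 alone held 9896 CPM of Prm1 and 6567 CPM of Tnp1, and without it the HFD means were 565 ± 420.4 and 344 ± 272 (SD, n = 7). In HFD 4 and HFD 8, 76.1% and 74.96% of reads fell in no annotated feature, against 58.0% to 67.9% in the other 14 libraries, and 8.02% and 9.16% fell in genes, against 10.3% to 20.1%. Transcripts of olfactory receptors, a negative control, summed to 170.5 and 173.5 CPM in these 2 libraries and to at most 94.1 CPM elsewhere.

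**Figure D1:**
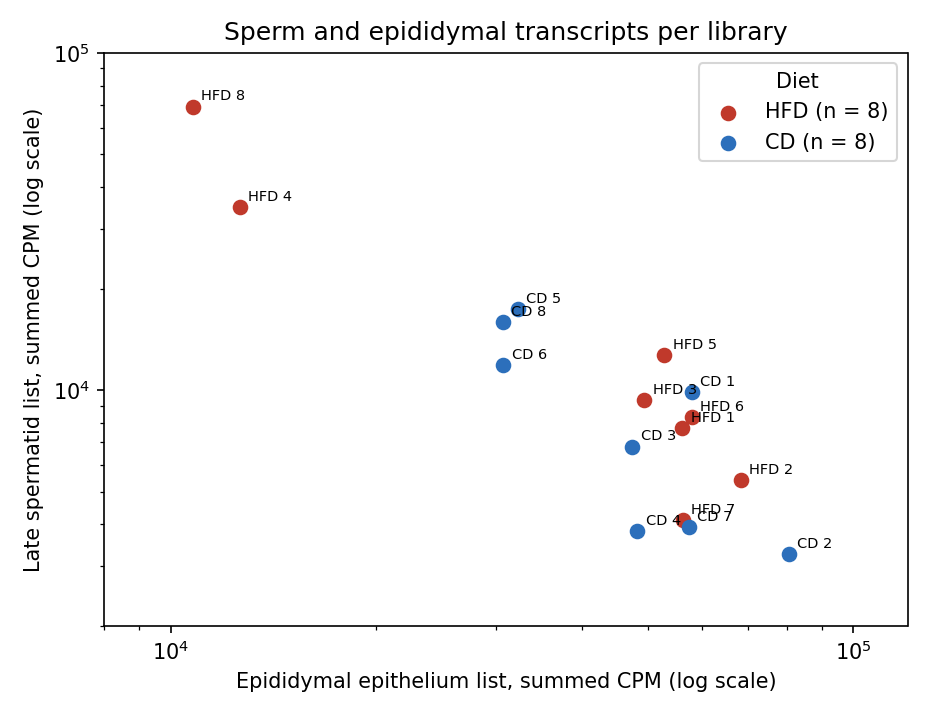
Summed CPM of the late spermatid list (y axis, log scale) against that of the epididymal epithelium list (x axis, log scale), with 1 point per library coloured by diet. HFD 8 and HFD 4 stand apart at 69302 and 34901 CPM of late spermatid transcripts, and the other 14 libraries lie at or below 17375.

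The makeup of the RNA did not differ detectably between the diets. Late spermatid transcripts summed to 18976 CPM ± 22564 in HFD and 9094 ± 5566 in CD (SD, n = 8), with an exact permutation p of 0.294 on the log2 scale, and epididymal transcripts to 45552 ± 21598 and 48140 ± 17255 (exact permutation p = 0.530). Without HFD 4 and HFD 8 the differences in log2 units went from 0.66 to -0.02 for late spermatid transcripts (exact permutation p = 0.958) and from -0.26 to 0.31 for epididymal transcripts (exact permutation p = 0.170), with single libraries left out giving 0.30 without HFD 8 and 0.44 without HFD 4 for the former, and 0.0021 without HFD 8, -0.03 without HFD 4 and -0.14 without CD 2 for the latter. Of the 31 composition measures, 0 passed after Benjamini-Hochberg adjustment. The smallest unadjusted exact permutation p was 0.0553, for the insulin, IGF and adipokine signalling list, with 1756 CPM ± 280.4 in HFD and 1978 ± 111 in CD, and its adjusted value was 0.572. That list stood at 1366 CPM in HFD 4 and 1377 CPM in HFD 8, and the difference in log2 units went from -0.19 to -0.07 without these 2 libraries. The chromatin and DNA methylation list, at 2618 CPM ± 541 in HFD and 2994 ± 144 in CD, had an exact permutation p of 0.0702, and its difference in log2 units went from -0.22 to -0.14 without HFD 8 and -0.05 without HFD 4 and HFD 8 (exact permutation p = 0.300).

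Marker lists of other cells had low sums. Leukocyte genes summed to 1067 CPM ± 416 in HFD and 811 ± 321 in CD (SD, n = 8), and genes of stroma, endothelium and muscle to 861 ± 359.9 and 729.5 ± 275.7. Sertoli cell genes summed to 196 CPM ± 42.3 and 204 ± 23.2, Leydig cell genes to 133 ± 19.9 and 122 ± 41.6, and spermatogonial genes to 152 ± 81.0 and 117 ± 39.5. Accessory gland genes reached 29.2 CPM ± 16.6 and 34.5 ± 18.1, erythroid genes 59.3 ± 57.4 and 55.9 ± 24.97, and adipocyte genes 68.7 ± 60.3 and 47.2 ± 18.7. Among the negative controls, liver-secreted genes stood at 116 CPM ± 27.4 and 112 ± 26.1, and olfactory receptors at 91.3 ± 51.6 and 57.1 ± 23.4. Mean sums of the accessory gland, erythroid and adipocyte lists lay below that of the liver control in both diets. That sum is no background level, since 2 of its 15 genes passed the filter. With TMM scaling, Fga had 54.3 CPM ± 32.4 in HFD and 67.4 ± 32.7 in CD. Trf, also in the Sertoli cell list, had 56.0 ± 15.1 and 39.4 ± 19.4. Exact permutation tests gave p from 0.0909 for olfactory receptors to 0.869 for erythroid genes. HFD 4 held 200.3 CPM of erythroid genes, where Alas2 alone had 202 CPM with TMM scaling, and HFD 8 held 216 CPM of adipocyte genes, where Lipe, which has a testis form, had 197 CPM with TMM scaling.

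Differences of these cell lists moved when 1 library was left out. In log2 units, the leukocyte difference was 0.40, and 0.23 without CD 2. The stromal difference was 0.23, and 0.11 without either HFD 4 or CD 2 and 0.13 without HFD 8. The spermatogonial difference was 0.27, and 0.11 without HFD 6 and 0.14 without CD 8. Leydig cell genes differed by 0.17, and by 0.11 without CD 2 and 0.28 without CD 1. Accessory gland genes differed by -0.41, and by -0.14 without HFD 4, -0.17 without HFD 8 and -0.23 without CD 1. The adipocyte difference was 0.36, and 0.08 without HFD 8 and 0.20 without CD 3. Values near 0 turned sign: Sertoli cell genes, at -0.08, ranged from -0.13 without HFD 7 to 0.02 without HFD 4, and liver genes, at 0.05, from -0.03 without HFD 7 to 0.14 without HFD 4. Erythroid genes, at -0.07 though the mean CPM was higher in HFD, ranged from -0.37 without HFD 4 to 0.045 without CD 6. Without both HFD 4 and HFD 8 the differences were 0.20 for leukocyte, -0.03 for stromal, 0.08 for Sertoli cell, 0.54 for spermatogonial, 0.21 for Leydig cell, 0.17 for accessory gland, -0.39 for erythroid, 0.04 for adipocyte, 0.19 for liver and 0.25 for olfactory receptor genes, the last from 0.61.

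Over 13149 genes, the libraries did not separate by diet. Diet accounted for 8.70% of the squared distance between libraries, with a pseudo-F of 1.33 and an exact permutation p of 0.247. Mean distance within HFD was 155 and within CD 106, a difference of 49.1 with a two-sided exact permutation p of 0.375. Leaving out HFD 4 gave a pseudo-F of 0.87 and a difference of 24.0, and leaving out HFD 8 gave 0.92 and 32.6. The first principal component held 51.1% of the variance and placed HFD 4 at 192 and HFD 8 at 152, with CD 5 next at 22.5. Without these 2 libraries the HFD distance was 97.6 and the difference -8.04 (exact permutation p = 0.436).

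**Figure D2:**
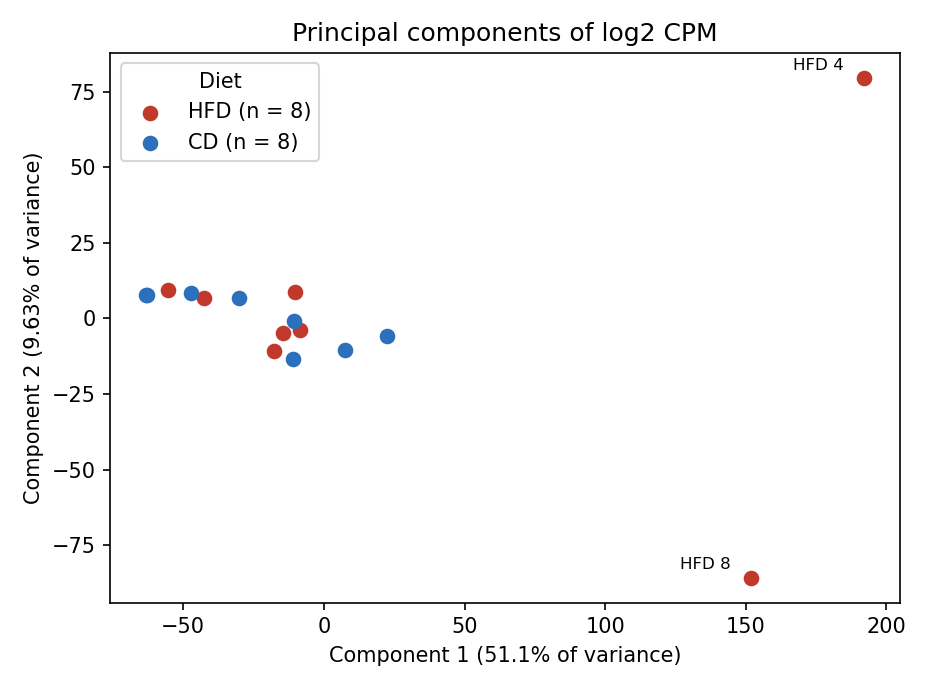
Principal components of log2 CPM, component 1 (51.1% of the variance) on the x axis and component 2 (9.63%) on the y axis, with 1 point per library coloured by diet. HFD 4 and HFD 8 lie at 192 and 152 on component 1, and the other 14 libraries of both diets lie together at 22.5 or below.

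The diet comparison of single genes put 0 of 13149 genes past the threshold with edgeR. The gene with the smallest p was Apoh, which encodes a plasma glycoprotein that binds phospholipids (chromosome 11, 108343354 to 108414396 on GRCm38, a protein-coding gene that overlaps Prkca on the other strand). It had 12.3 CPM ± 14.5 in HFD and 1.498 ± 1.18 in CD (SD, n = 8), a log2 fold change of 2.98 ± 0.65 (SE) with an edgeR adjusted p of 0.434. Rnf26, a ubiquitin ligase gene (chromosome 9, 44095631 to 44113517, overlapping 6 annotated genes), had 8.58 CPM ± 2.92 in HFD and 17.0 ± 1.36 in CD, a log2 fold change of -0.98 ± 0.24 (SE) with an edgeR adjusted p of 0.434. Spag11b, an epididymal gene with beta-defensin domains (chromosome 8, 19140759 to 19143010, in a gene family whose reads the counting could split), had 226 CPM ± 276 in HFD and 12.1 ± 14.5 in CD, a log2 fold change of 4.22 ± 1.11 (SE) and the same edgeR adjusted p of 0.434. The HFD mean of Apoh was 7.99 CPM without HFD 4. For Spag11b the HFD mean was 163 CPM without HFD 5, and the CD mean 7.33 CPM without CD 6. Its HFD values ran from 0.6 CPM in HFD 4 to 666 CPM in HFD 5, and 4 HFD libraries lay above the highest CD value of 45.5 CPM.

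With edgeR, 1482 genes had an unadjusted p under 0.05, against 657 expected by chance, and of these 1338 were higher and 144 lower in HFD. DESeq2 called 1 gene, Apoh, with an adjusted p of 0.0182, and limma-voom with quality weights called 0, with 500 genes at an unadjusted p under 0.05. Leaving out HFD 4 gave 516 such genes, leaving out HFD 8 gave 689, and leaving out both, a choice made after the data were seen, gave 292, of which 132 were higher and 160 lower in HFD.

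Among the 20 genes with the smallest p, none of which passed the threshold, 17 were higher and 3 lower in HFD. In 15 of the 17 the highest and next highest values were those of HFD 4 and HFD 8. Mrto4, which acts in ribosome assembly, had 47.0 CPM ± 45.0 in HFD and 14.6 ± 3.46 in CD. Kat8, a histone acetyltransferase, had 58.9 CPM ± 40.6 and 26.5 ± 4.33. Cftr, a chloride channel, had 22.0 CPM ± 15.2 and 7.72 ± 3.27. Calr3, a calreticulin of male germ cells, had 23.1 CPM ± 29.3 and 3.97 ± 2.48. Cst13, a cystatin family gene, had 13.9 CPM ± 19.1 and 2.10 ± 1.66. Without HFD 8 the HFD means of Calr3 and Cst13 were 14.99 and 7.90 CPM. The remaining 10 genes with higher values in HFD, Aven, 1700112J05Rik, Pom121l12, 1700026D11Rik, 4930406D18Rik, 1700017J07Rik, Zscan12, Gprc5b, BC089491 and Tas1r1, had log2 fold changes between 1.09 for Zscan12 and 2.76 for 4930406D18Rik. The genes at lower values in HFD were Rnf26, Pbld2 with 9.19 CPM ± 5.89 and 26.9 ± 8.20, and the zinc finger gene Zfp641 with 1.74 ± 1.11 and 6.27 ± 5.17. Without HFD 4 and HFD 8, log2 fold changes of 9 of the 20 were no more than 50% of their value. Apoh then stood at 1.66, Rnf26 at -0.88, Pbld2 at -1.21, Zfp641 at -1.94 and Spag11b at 4.08, and the other 15 genes lay between 0.58 for Zscan12 and 1.43 for Gprc5b.

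**Figure D3:**
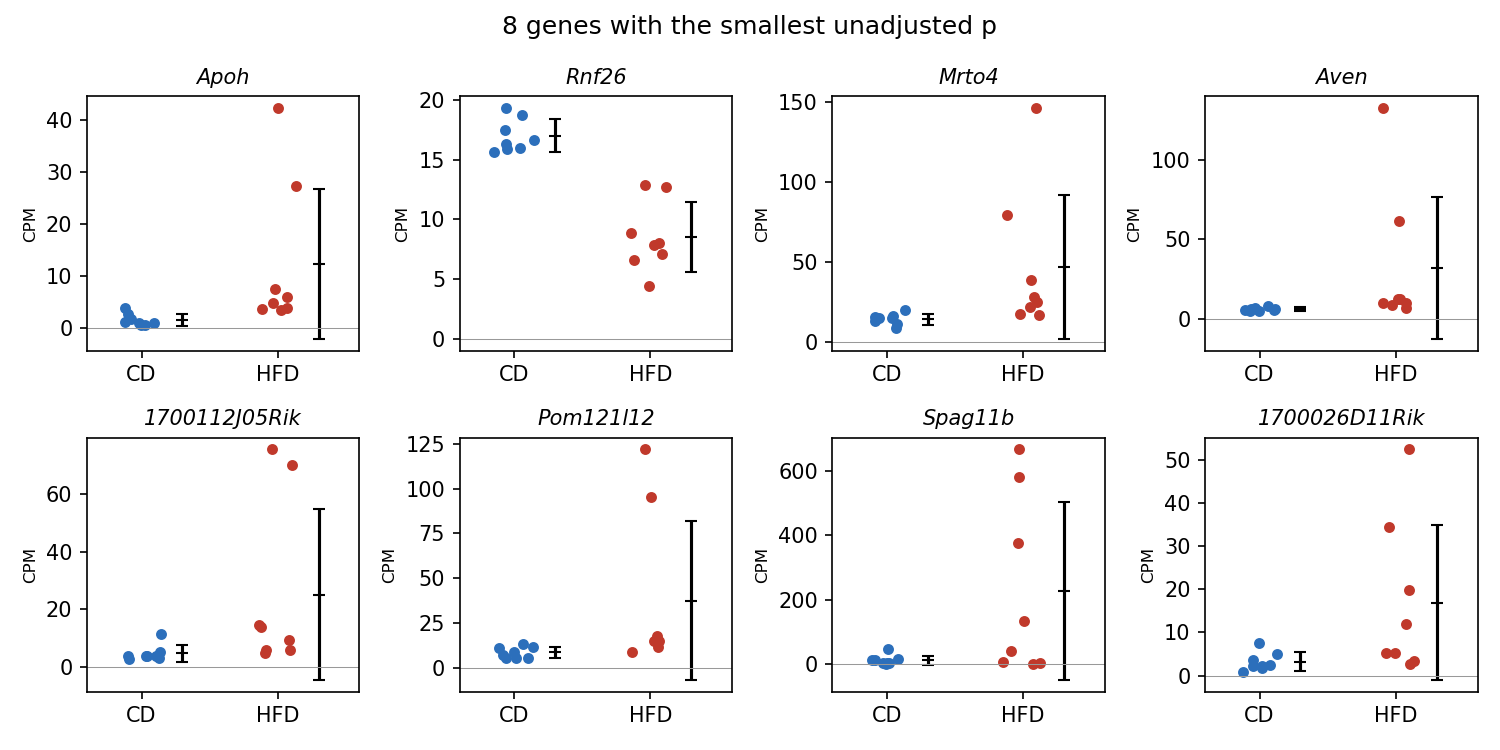
CPM per library (y axis, linear) by diet for the 8 genes with the smallest unadjusted p, with each point a library and bars at the mean ± SD (n = 8). The HFD means of Apoh, Mrto4 and Aven sit far above most HFD points because HFD 4 and HFD 8 lie highest, whereas every HFD value of Rnf26 is below every CD value.

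Germ cell lists held the largest median differences between the diets, and none passed. The 40 tested late spermatid genes had positive log2 fold changes, with a median of 1.48, and 0 passed over all genes tested or adjusted over the list alone. Among them Smcp had 1992 CPM ± 2057 in HFD and 1293 ± 884 in CD, Odf1 1703 ± 1624 and 1295 ± 848, and Prm2 1652 ± 2471 and 743 ± 556 (SD, n = 8). Without HFD 8 the HFD mean of Prm2 was 794 CPM ± 498 (SD, n = 7). With an estimated correlation of 0.80 between these genes, camera gave an adjusted p of 0.849. Without HFD 4 and HFD 8 the median was 0.01. Of 26 meiotic genes, 24 had positive values with a median of 0.84, among them Mael with 559 CPM ± 681 and 218 ± 119, Ddx4 with 119 ± 146 and 47.5 ± 29.5, and Syce2 with 191 ± 229 and 105 ± 80.2. Without HFD 4 the HFD means of Mael and Ddx4 were 353 and 78.5 CPM. Camera gave adjusted p = 0.849 with an estimated correlation of 0.49, and the median without HFD 4 and HFD 8 was -0.09. The 4 tested spermatogonial genes, among them Gfra1, Kit and Zbtb16, had a median near 0 whose sign changed with the scaling, and were too few for a list test. Without HFD 4 and HFD 8 the list could be tested, with a median of -0.38 and a camera adjusted p of 0.899. The list's sum without these 2 libraries went the other way, by 0.54 in log2 units.

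Epididymal genes showed no shared direction. Of 36 tested, 12 had positive and 24 negative log2 fold changes, with a median of -0.15, which was 0.18 without HFD 4 and HFD 8. Adjusted over the list alone, 1 gene passed, Spag11b, and over all genes tested 0 did. Within each diet Spag11b was higher in libraries with high Gpx5, an epididymal gene taken up further below. In HFD it had 39.7 to 666 CPM in the 5 libraries with high Gpx5 and 0.6 to 5.8 in the 3 others. In CD it had 11.5 to 45.5 CPM in 4 and 1.3 to 4.1 in the other 4. Camera gave adjusted p = 0.941 with an estimated correlation of 0.32. Leukocyte genes had 18 of 20 positive values with a median of 0.52, among them Lyz2 with 481 CPM ± 179 in HFD and 339 ± 159.98 in CD, and genes of stroma 14 of 16 with a median of 0.20, among them Sparc with 252 ± 147 and 197 ± 74.3. Camera gave adjusted p = 0.849 with an estimated correlation for both. In HFD 4 and HFD 8, leukocyte genes stood 1.37-fold and 1.99-fold above the median of the other 14 libraries, and stromal genes 2.25-fold and 2.03-fold. Without these 2 libraries the medians were 0.10 for leukocyte genes and -0.16 for genes of stroma. Sertoli cell genes, among them Trf and Sox9, had a median of -0.03 over 7 genes (adjusted p = 0.861 with an estimated correlation), and of 0.06 without the 2 libraries. Adipocyte and Leydig cell lists had 4 tested genes each, and accessory gland, erythroid and liver lists 2 each, too few for a list test, and 0 genes of these lists passed over all genes or adjusted over the list alone.

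No metabolic, stress or signalling list passed. The glycolysis list had a median of 0.25 over 25 genes, 16 of them positive. Its 3 most abundant genes were the sperm isozymes Ldhc, with 1510 CPM ± 1841 in HFD and 573 ± 303 in CD and Pgk2, with 836 ± 895 and 403 ± 252, and Gapdh of other cells, with 277 ± 128 and 341 ± 47.2. In HFD 4 and HFD 8 this list stood 3.62-fold and 3.70-fold above the median of the other 14 libraries. Fatty acid oxidation genes had a median of -0.01 (26 genes), nuclear oxidative phosphorylation genes 0.0023 (79 genes), and sterol and fat synthesis genes -0.17 (28 genes). Antioxidant genes had a median of -0.10 (29 genes), heat shock and ER stress genes -0.24 (24 genes), and inflammation genes -0.04 (12 genes). Insulin, IGF and adipokine signalling genes had a median of -0.26 over 20 genes, 16 of them negative, among them Igf1r with 188 CPM ± 90.1 and 215 ± 49.7. Without HFD 4 and HFD 8 the medians were 0.01 for glycolysis, 0.0040 for fatty acid oxidation, 0.05 for oxidative phosphorylation, 0.03 for sterol and fat synthesis, 0.03 for antioxidant, -0.03 for heat shock, 0.18 for inflammation and -0.08 for insulin signalling genes. Camera with an estimated correlation gave adjusted p = 0.849 for these lists, except 0.979 for inflammation.

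No list of chromatin, translation or RNA genes passed. Chromatin and DNA methylation genes had a median of -0.11 over 37 genes, imprinted genes -0.08 over 15, cytosolic ribosomal proteins -0.10 over 79, translation factors -0.02 over 62, proteasome genes 0.03 over 47, structural and nuclear noncoding RNA 0.07 over 7, and olfactory receptors 0.24 over 6. Without HFD 4 and HFD 8 these medians were -0.06 for chromatin genes, -0.0065 for imprinted genes, 0.02 for ribosomal proteins, -0.03 for translation factors, 0.05 for the proteasome, 0.07 for noncoding RNA and 0.05 for olfactory receptors. Adjusted p with an estimated correlation was 0.849 for chromatin genes, ribosomal proteins and olfactory receptors, 0.857 for imprinted genes, 0.861 for the proteasome, 0.897 for translation factors and 0.961 for noncoding RNA, whose median was positive while the test's direction was down. In HFD 4 and HFD 8 ribosomal protein genes stood at 18540 and 24292 CPM, against 29102 to 39270 in the other 14. Of the 21 lists tested, camera called 0 with an estimated correlation. A preset correlation of 0.01 called 5, with late spermatid, meiotic and leukocyte genes higher and the insulin and heat shock lists lower in HFD, none of which held with the estimated one. Adjusted over the list alone, 0 genes passed in the 20 tested lists other than the epididymal one.

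**Figure D4:**
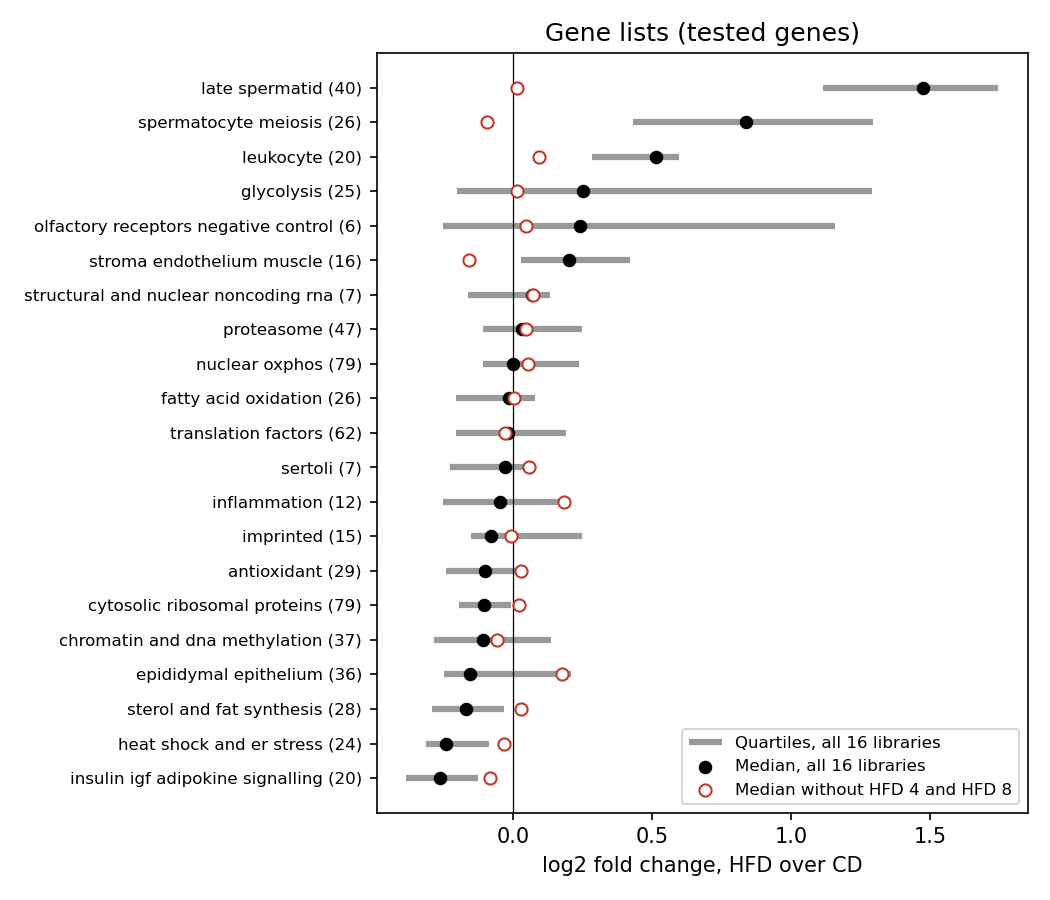
Median log2 fold change, HFD over CD (x axis), of each gene list with at least 5 tested genes (y axis, number of genes in brackets), with grey bars for the quartiles over genes, black points for all 16 libraries and open points without HFD 4 and HFD 8. The late spermatid median moves from 1.48 to 0.01 and the meiotic median from 0.84 to -0.09.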

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

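The tests of HFD 4 and HFD 8 and of the excess of small p in this part were chosen after the results were seen. A library was listed where its gap to the nearest library of its diet, divided by the range, exceeded Dixon's critical value for a group of 8. This met 34 cases among 276 groups of values, and chance alone lists about 1 group in 20, or 13.8 here. On log2 values the number was 16. HFD 4 and HFD 8 gave 9 and 7 of the 34.

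HFD 8 held the highest values of its diet for late spermatid transcripts with 69302 CPM, Odf1 with 5497 CPM, Prm2 with 7660 CPM, Gprc5b with 47.4 CPM, Cst13 with 56.1 CPM, adipocyte transcripts with 216 CPM and Lipe, a lipase with a testis form, with 197 CPM. HFD 4 held the highest values for Aven with 133 CPM, 4930406D18Rik with 82.7 CPM, 1700017J07Rik with 48.2 CPM, Zfp641 with 4.2 CPM, Olfr112 with 46.4 CPM, Olfr701 with 55.3 CPM, summed erythroid transcripts with 200.3 CPM, and the erythroid genes Alas2, of haem synthesis, with 202 CPM and Slc4a1 with 21.4 CPM. Single genes are scaled with TMM factors and sums are not, so these values do not add up. Among the other HFD libraries, HFD 3 had 30.7% of reads not uniquely aligned.

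CD 2 had 7.78 M gene counts and 20.1% of reads in genes, each the highest of its diet, with 17613 CPM of Lcn5, 11955 CPM of Itm2b, 11704 CPM of B2m and 277 CPM of Psma7, and the lowest value of the chromatin list, 2691 CPM. CD 1 had 75.2 CPM of accessory gland transcripts and 57.5 CPM of Spinkl, and CD 3 had 171 CPM of liver transcripts. CD 8 had 11.5 CPM of 1700112J05Rik, 46.0 CPM of Lipe and the lowest Mtor, 188 CPM. CD 5 had 278 CPM of Syce2 and 15.3 CPM of Olfr112, CD 4 had 542 CPM of Kmt2c, and CD 6 had 45.5 CPM of Spag11b.

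HFD 4 and HFD 8 had log2 ratios of late spermatid to epididymal transcripts of 1.47 and 2.68, against -4.62 to -0.89 in the other 14 libraries, with 76.1% and 74.96% of reads in no feature against at most 67.9%, and 2.87-fold and 2.92-fold the others' median of olfactory receptor transcripts. Low depth is argued against for HFD 8, since the highest ratio among the 3 other libraries shallower than HFD 8 was -2.05. HFD 4 had the fewest gene counts of all, 1882555, and no library of like gene count was at hand. By all reads in its column, 23.5 M, it was not the shallowest. HFD 5 and HFD 7 had 21.1 M and 21.3 M reads and ratios of -2.05 and -3.77. These values argue against the number of reads as the reason for HFD 4. Its low gene count, with 8.02% of reads in genes, stays open. Late spermatid genes lay above leukocyte and stromal genes by 1.68 in HFD 4 and 1.92 in HFD 8 (median log2 change), with an SD of 0.54 in the other 14. This cannot decide whether loss of epididymal cells alone accounts for the pattern. The 2 libraries were picked for high late spermatid sums, and leukocyte and stromal cells could be lost together with epididymal tissue. No shift of this size was seen in the other 6 HFD libraries, whose highest ratio was -2.05 against a highest CD ratio of -0.89. HFD 4 and HFD 8 were picked on these sums, so this describes the libraries and is no test of diet. A larger share of sperm or of earlier germ cells, a different preparation or RNA quality of these 2 libraries, for which the labels give no batch, or a response of some animals to the diet may each account for the pattern, and these stay open as untested.

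The excess of genes at an unadjusted p under 0.05, 1482 in number, may come from HFD 4 and HFD 8. Leaving out both gave 292 genes, and leaving out any of the other 27 pairs of HFD libraries gave 538 to 2481, which argues against fewer libraries as the reason. Of 100 splits of the libraries, the real one included, 25 gave at least 1482 genes, so chance cannot be excluded, and the highest of the other splits gave 2892. HFD 4 and HFD 8 were on one side in 40 of the other 99 splits, with a median of 1633 genes, and apart in 59, with a median of 231 genes and at most 580. With the log2 total of gene counts as a covariate 286 genes remained. That total was lowest in HFD 4, where 8.02% of reads fell in genes. The covariate thus cannot separate depth from the makeup of that library, and a link of the excess to depth stays open. For genes and for gene lists past the threshold, the real value and the highest of the other splits were 0. With a real value of 0 any split gives as many, 100 of 100 here, so these splits cannot exclude chance and carry no information on it.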

How the results depend on the processing

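The comparisons without HFD 4 and HFD 8, with the ratio covariate and with the newer fit were chosen after the data were seen. The count of genes past the threshold was 0 in 32 alternatives, an adjusted p under 0.1 included, and 1 (Apoh) with DESeq2, which tested 14518 genes, and the cause was not tested. DESeq2 gave 33 genes at an adjusted p under 0.1. The count of lists past the threshold was 0 in 23 alternatives and 5 with the preset correlation of 0.01, for lists with estimated correlations of 0.14 to 0.80. Composition stayed at 0 measures in 18 alternatives, and the pseudo-F and the distance difference stayed short of the threshold in 20 each. Adjusted p of Apoh ranged from 0.0182 to 0.9997 over its alternatives. Of 3344 values of named genes under alternatives, 3343 stayed on their side of the threshold and 1 (Apoh, DESeq2) passed it. This follows from the counts of genes past the threshold and does not measure how stable the fold changes were. Without HFD 4 and HFD 8, 9 of the 20 genes with the smallest p kept no more than 50% of theirs. Whole profiles gave no clear sign that title numbers pair the libraries: correlations of same-numbered libraries ran from -0.40 to 0.61, and 2 of 8 numbers matched best with their own. A pairing with a weaker effect could not be seen in this way. With the replicate block the count of genes was 0, with 314 at an unadjusted p under 0.05, the count of lists 0, and the permutation p of the pseudo-F 0.359. Genes at an unadjusted p under 0.05 numbered 2518 with no low-count filter, 2258 with DESeq2, 500 with quality weights, 442 with 2 surrogate variables, 286 with the log2 total and 602 with the ratio covariate, and 516 to 2020 with 1 library left out. List medians changed sign with the scaling for spermatogonial, oxidative phosphorylation, fatty acid oxidation, translation factor and proteasome genes. In data simulated at these libraries' depths, 2-fold changes were recovered for 3 of 50 genes and 4-fold changes for 34 of 50. Other depths and correlated genes were not simulated.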

Other observations

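The tests in this part were chosen after the values were seen. Some genes of the initial segment and caput, the upstream stretches of the epididymis, were high in some libraries of both diets and low in others. Gpx5, a secreted glutathione peroxidase of the caput (chromosome 13, 21286429 to 21292731 on GRCm38), had 246 to 7427 CPM in 5 HFD and 4 CD libraries and 1.39 to 28.4 CPM in 3 HFD and 4 CD libraries. Across these 9 and 7 libraries, median CPM was 1028 and 391 for Spag11a, 320 and 109 for Ros1, 83.5 and 6.30 for Defb15, 58.0 and 2.47 for Defb41, 46.4 and 3.34 for Spag11b, 26.97 and 1.06 for Cst11, 21.02 and 0.557 for Defb18, and 6.21 and 0 for Rnase10. The other 5 of the 13 genes set beside Gpx5 had low medians in both sets, 2.95 and 1.58 for Lcn8, 1.12 and 0.353 for Adam28, 0.561 and 0 for Lcn10, 0.280 and 0 for Cst12, and 0 and 0 for Lcn9.

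Different stretches of epididymis in the preparations may account for the range of Gpx5. Diet cannot by itself, since Gpx5 differed 1394-fold within the CD libraries and 862-fold within HFD, and the exact permutation p between diets was 0.361. Read depth is argued against, as gene counts of the 2 sets overlapped. They ran from 1882555 to 4760694 in the libraries with low Gpx5 and from 2721022 to 7783981 in those with high Gpx5. The library with the fewest reads of Gpx5, CD 3, had 5 counts of it among 3589693 gene counts. Within the 9 libraries with high Gpx5, it went with the summed CPM of 13 other initial segment and caput genes (Spearman's rho 0.63, exact permutation p = 0.0760, adjusted p = 0.152 over 2 groups; Pearson's r 0.63, permutation p = 0.0673, and 0.47 without the 2 libraries farthest from the median), and within the other 7 rho was -0.14 (permutation p = 0.783; r 0.05, permutation p = 0.921, and -0.37). That relation missed the threshold in both groups. The groups were cut at a gap in Gpx5, which narrows its range within each, and the relation over all 16 libraries was not tested. Between the groups, the 13 genes summed to 853 to 2429 CPM with high Gpx5 and to 148 to 1289 CPM with low Gpx5. The epididymal explanation stays open.

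A diet difference that separates genes completely was tested as a hypothesis. Rnf26 was the 1 gene of 13149 whose libraries did not overlap, with a highest HFD value of 12.9 CPM and a lowest CD value of 15.6 CPM. Chance gives 2.04 such genes, 4183 of the 6435 splits of the libraries gave at least 1, and the highest of the other splits gave 176, so chance cannot be excluded. That split set HFD 1, HFD 3, HFD 4, HFD 6, HFD 8, CD 1, CD 5 and CD 6 against the rest. Meiotic transcripts summed to 911 to 4716 CPM in the libraries named and to 349 to 804 CPM in the rest. Late spermatid sums overlapped, with 7722 CPM in HFD 1 and 15882 CPM in CD 8 of the other side. Whether germ cell transcripts set that split apart was not tested.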
